A study of Mus musculus with 24 samples.

How the data were processed

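Small RNA was sequenced from 24 mouse liver samples, 8 in each of 3 groups (AM132, AM608 and RCD). Per the labels, C57Bl/6J mice were kept on regular chow or on a high fat diet for 11 weeks. Obese mice received 3.3 mg/kg of an LNA oligonucleotide intravenously on 3 days running, a 16-mer against miR-132 or a 15-mer against miR-608, and livers were taken 7 days later. Hypothalamus samples were not analysed here. Per the labels' protocols, RNA was extracted with the miRNeasy Mini Kit, RIN was above 8.4, and libraries were made from 300 ng of total RNA with the NEBNext small RNA kit and run on a NextSeq 500. The values are raw read counts as deposited by the authors, in one table of mature miRNAs (1908 names, 584 of them without a count in any library) and one of tRFs (8456 sequences, named by the licence-plate code of their sequence). FastQC is the only tool named, per the submitters' processing notes. The aligner, adapter trimming and genome build are not given in the sources used here, and neither is the rule by which reads were assigned to miRNAs or tRFs, which could move counts between near-identical sequences. The NEBNext kit ligates adapters to 5′ phosphate and 3′ hydroxyl ends, so fragments with other ends are counted poorly, and PCR reads were counted without molecular identifiers as far as the labels say.

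Samples were grouped by their titles, and columns were matched to samples by group and number in the column names. No pair of libraries within a group agreed within sampling noise (lowest chi-square per degree of freedom 25.7 for miRNAs and 1.88 for tRFs over 84 pairs each). The comparisons, tests, alternatives, miRNA lists and the rule for named features were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3, with the robust quasi-likelihood fit, TMM factors, the filterByExpr filter, group as the only term and all 24 libraries in the fit. Benjamini-Hochberg adjustment ran over the 421 tested miRNAs or 295 tested tRFs, with a threshold of 0.05. An SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. CPM values use the TMM-scaled sum of counts in tested features of the table the feature is in. Tested tRFs held 48.4% of the tRF counts of AM132 library 8 and 87.0 to 90.4% in the other libraries, so tRF CPM values of AM132 library 8 lie about 1 log2 unit above its shares of all tRF counts.

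Lists were tested with camera of limma 3.58.1 on log2 CPM (prior of 2 counts) with a preset correlation of 0.01, adjusted over lists and comparisons, and again with an estimated correlation. Of 22 miRNA lists written, 18 had at least 3 tested members; 123 of the 167 listed miRNAs were tested. Many listed miRNAs are made by more than one cell type of the liver. The sums of LysTTT tRFs (log2 CPM, prior of 0.5 counts) and the log2 ratio of tRF to miRNA counts were compared by two-sided exact permutation tests over 12870 assignments. Correlations were tested over all 40320 pairings within each group. The relation between the changes in AM132 against AM608 and in AM608 against RCD was set beside 50 simulations of unchanged groups and beside 70 splits of the AM608 libraries.

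tRF names were decoded to sequences, and all 8456 names encoded back to themselves. Parent tRNAs were assigned by exact match to 38 nuclear tRNA sequences of 32 isoacceptors written from general knowledge after the tables had been seen, because the reference used here gave nuclear tRNA genes without their sequences. All 38 passed a test of stem pairing. A match was found for 4554 tRFs with 87.3% of the counts, and 4060 with 65.0% of the counts matched 1 isoacceptor. LysTTT took 232 tRFs with 4.01% of the counts. No tRF matched any of the 22 mitochondrial tRNAs searched. A tRF was called 5′, 3′ or internal by its place in the parent, and lists of tRFs needed 5 tested members, which 29 met. A parent copy that was not among the 38 sequences could change an assignment. Coordinates are from GENCODE M21 and, for LysTTT genes, from RefSeq, both on GRCm38; this is the reference used here, not a build stated for the counts.

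The fit was tested on simulated counts with 200 changed features in each of 5 simulations per comparison. Of tested miRNAs changed by a log2 fold change of 1, 81.0% (AM132 against AM608), 79.5% (AM608 against RCD) and 79.4% (AM132 against RCD) were recovered. At a log2 fold change of 2, 97.7%, 98.3% and 96.7% were recovered. For tRFs, with far fewer counts, the shares at a log2 fold change of 1 were 58.3%, 57.1% and 41.7%, and at 2 they were 100%, 88.0% and 95.8%. False calls made up 2.49%, 6.21% and 6.08% of miRNA calls and 2.13%, 5.56% and 0% of tRF calls.

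The text always names miR-132-3p, miR-132-5p, miR-212-3p, miR-212-5p, miR-194-5p, miR-194-2-3p, miR-192-5p and miR-122-5p. For each comparison it names from the called miRNAs the 10 higher and 10 lower with the smallest p, and from the called tRFs the 4 higher and 4 lower. It further names the 3 LysTTT tRFs, 5 miRNAs and 3 tRFs with the highest mean CPM, and up to 4 members of a list with the smallest p. Other features were chosen after their values had been seen and are said to be so, except those that a count or a set of miRNAs in the text consists of.

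Alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE factors, library totals, no filter, a filter at a mean CPM of 10, only the 2 groups compared, the replicate number as a block, each library left out in turn, and for tRFs the library sizes of the miRNA table and counts summed per isoacceptor. Without RCD library 3 and AM132 library 8 was added after the data had been seen, as were list medians under library totals, RLE factors and the library sizes of the miRNA table. Sequence matches to the oligonucleotide targets used miR-132-3p and miR-608 sequences written from general knowledge. They were scored on the side of the hairpin that holds the arm (29 to 64 nt), or the whole hairpin for the 27 miRNAs whose name gives no arm, as no mature sequences were used here, and scores adjusted for length were added after the data had been seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.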

Results

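Small RNA libraries from the livers of 24 C57Bl/6J mouse samples were compared in 3 groups of 8. AM132 samples came from mice made obese on a high fat diet and injected with a locked nucleic acid (LNA) antisense oligonucleotide against miR-132. AM608 samples came from obese mice injected with an LNA oligonucleotide against miR-608, a primate miRNA that serves as the control target. RCD samples came from lean, uninjected mice on regular chow. AM132 against AM608 compares the oligonucleotide against miR-132 with that against miR-608 in the obese liver. As the 3 groups hold no uninjected obese mice, a difference can come from either oligonucleotide. AM608 against RCD sets obese against lean liver, with diet and injection differing together. AM132 against RCD asks how far the treated obese liver lay from the lean one.

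Counts of mature miRNAs totalled 5926983 to 8734721 per library in AM132, 6855571 to 8532049 in AM608 and 5689143 to 8380591 in RCD. Counts of transfer RNA fragments (tRFs) were far fewer, at 25849 to 80578 in AM132, 29889 to 46567 in AM608 and 20580 to 39077 in RCD. A library held 709 to 897 miRNAs and 1375 to 4099 tRFs with a count. The most abundant miRNA was miR-122-5p, the main miRNA of hepatocytes, at 234700 ± 62250 CPM (counts scaled to the library size) in RCD, 212300 ± 31670 in AM608 and 284800 ± 33650 in AM132 (mean ± SD, n = 8 each). It was followed by miR-148a-3p, miR-21a-5p, miR-192-5p and let-7f-5p. The most abundant tRF was tRF-26-86J8WPMN1EE, a 26-nt fragment from the 5′ end of tRNA-GluTTC, at 184900 ± 65700 CPM of the tRF counts in RCD. Next came the 18-nt 3′ fragments tRF-18-8R6Q46D2 and tRF-18-8R6546D2 of tRNA-Ala. The p-values measure the spread between these samples, since the labels number the samples without tying each to an animal of its own. Floors for undetected miRNAs cover counting error only.

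miR-132-3p, the target of the injected oligonucleotide, was not counted in any of the 8 AM132 libraries. Its level was 23.3 ± 7.01 CPM in AM608 (range 13.1 to 36.4, n = 8) and 20.7 ± 12.7 CPM in RCD (range 10.4 to 50.6, n = 8). With a floor of 3 counts over the AM132 group, 0.0598 CPM, miR-132-3p was at least 390-fold lower than in AM608 and at least 346-fold lower than in RCD (edgeR adjusted p = 3.61e-10 and 3.77e-10). These bounds are on counted reads, as loss in the liver and masking during library preparation cannot be separated here. AM608 and RCD were not told apart for miR-132-3p (edgeR adjusted p = 0.686). The other products of the locus were far less affected: miR-132-5p, from the opposite arm of the same precursor, had a log2 fold change of −0.30 (SE 0.17, edgeR adjusted p = 0.309) in AM132 against AM608. miR-212-3p, which has the same seed as miR-132-3p, was lower by a log2 fold change of −1.61 (SE 0.521, edgeR adjusted p = 0.0441), whereas miR-212-5p did not pass (−0.46, edgeR adjusted p = 0.13). The miR-212-3p call was lost when any of 11 single libraries was left out (AM132 1, 3, 4, 5, 6 or 8, AM608 1, 3, 5, 7 or 8, edgeR adjusted p up to 0.103) and without a filter on low counts (0.0734). Between AM608 and RCD, 1 of the 4 products of the locus, miR-212-5p, was called, as higher in AM608. Its log2 fold change ran from 0.54 to 0.74 with each library left out in turn, and the call was kept each time. As a list, the 4 were not called there (camera adjusted p = 0.41). In GRCm38, Mir212 (chromosome 11, 75173388 to 75173478) and Mir132 (75173682 to 75173747) lie on the plus strand within the processed transcript 1700016P03Rik.

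A set of other miRNAs was lower in AM132 than in AM608, and fewer were higher. let-7a-1-3p, the passenger strand of a let-7 precursor, fell from 176.8 ± 14.2 CPM in AM608 to 11.96 ± 6.33 CPM in AM132 (n = 8 each), a log2 fold change of −3.89 (SE 0.247, edgeR adjusted p = 8.31e-12). Of the 9 tested let-7 passenger strands (3p arms, grouped after their values were seen) 7 fell, let-7c-1-3p and let-7i-3p not passing (0.10 and 0.27, edgeR adjusted p = 0.799 and 0.397), with let-7b-3p at −1.89 and let-7f-1-3p at −2.33 (edgeR adjusted p = 1.04e-08 and 1.99e-07). The 7 count let-7a-1-3p and let-7c-2-3p apart, though their values were nearly the same and may come from the same reads. miR-139-5p (Mir139, within Pde2a, GRCm38 chromosome 7, 101475376 to 101475443) fell from 832 ± 87.8 to 238 ± 88.9 CPM. miR-185-5p and miR-674-3p rose by log2 fold changes of 1.40 (SE 0.124) and 1.30 (SE 0.135).

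The edgeR test called 52 of 421 miRNAs in AM132 against AM608, 17 higher and 35 lower, of which 3 higher and 16 lower changed by a log2 fold change above 1 in size. For 28 of the 421 miRNAs the AM132 and AM608 values did not overlap, where chance gives 0.0155% per miRNA. With library totals in place of trimmed mean of M values (TMM) factors the split was 8 higher and 83 lower, and the median of all tested miRNAs shifted by −0.25, to −0.21. The calls of miR-3535, miR-30b-3p and miR-5099 were lost there (edgeR adjusted p = 0.153, 0.428 and 0.0998), and that of miR-30b-3p also without a filter on low counts (0.137). Besides miR-185-5p (edgeR adjusted p = 3.2e-09) and miR-674-3p (5.68e-08), the higher miRNAs with the smallest p included miR-187-3p (0.66, 4.05e-04), miR-192-5p (0.58, 8.16e-04), miR-194-2-3p (0.70, 6.27e-04), miR-3535 (0.45, 3.43e-03) and miR-148a-5p (0.52, 5.89e-03). miR-200b-5p (1.70, 5.94e-03), miR-30b-3p (0.35, 6.19e-03) and miR-5099 (0.63, 9.75e-03) were also higher by the edgeR adjusted p. Of the lower ones, miR-582-5p fell by 3.60 on the log2 scale (edgeR adjusted p = 8.52e-08), miR-676-5p by a log2 fold change of −1.24 (3.58e-07), miR-30e-3p by −0.80 (1.21e-07) and miR-25-3p by −0.67 (1.15e-06). let-7c-2-3p had nearly the same values as let-7a-1-3p, so the source of these reads is uncertain between Mirlet7a-1 (GRCm38 chromosome 13, 48538179 to 48538272) and Mirlet7c-2 (chromosome 15, 85706603 to 85706697). Mir185 lies in Tango2 (chromosome 16, 18327401 to 18327465) and Mir582 in Pde4d (chromosome 13, 109324744 to 109324824).

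miR-194-5p, named in the title of the series, averaged 20040 CPM in AM132, 15100 in AM608 and 14670 in RCD. Its log2 fold change of 0.41 (SE 0.144) in AM132 against AM608 did not pass the edgeR test (adjusted p = 0.0643), and AM608 did not differ detectably from RCD (0.04, edgeR adjusted p = 0.846). AM132 was higher than RCD by 0.45 (edgeR adjusted p = 0.0174), a call lost with library totals (0.12), without a filter (0.0818) and with only the 2 groups in the fit (0.0641). The call in miR-194-5p AM132 vs AM608 depended on the processing. It was reached with only the 2 groups in the fit (0.38, edgeR adjusted p = 8.14e-04), at a mean CPM of at least 10 (0.40, edgeR adjusted p = 0.0414) and with limma voom (0.45, limma adjusted p = 1.66e-04). It was also reached without RCD library 3 (0.38, edgeR adjusted p = 0.00976), and without RCD library 3 and AM132 library 8 (edgeR adjusted p = 0.014). It was missed with DESeq2 (0.0665) and, by the edgeR adjusted p, with RLE factors (0.0678), library totals (0.391), no filter (0.209) and the replicate block (0.0882). The clustered miR-192-5p was higher in AM132 at 78990 ± 7003 CPM against 52980 ± 6089 in AM608, as was miR-194-2-3p. Their loci, Mir192 (GRCm38 chromosome 19, 6264844 to 6264932) and Mir194-2 (6264643 to 6264728), are intergenic, and miR-194-5p is also made from Mir194-1 (chromosome 1, 185313319 to 185313385).

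**Figure D1:**
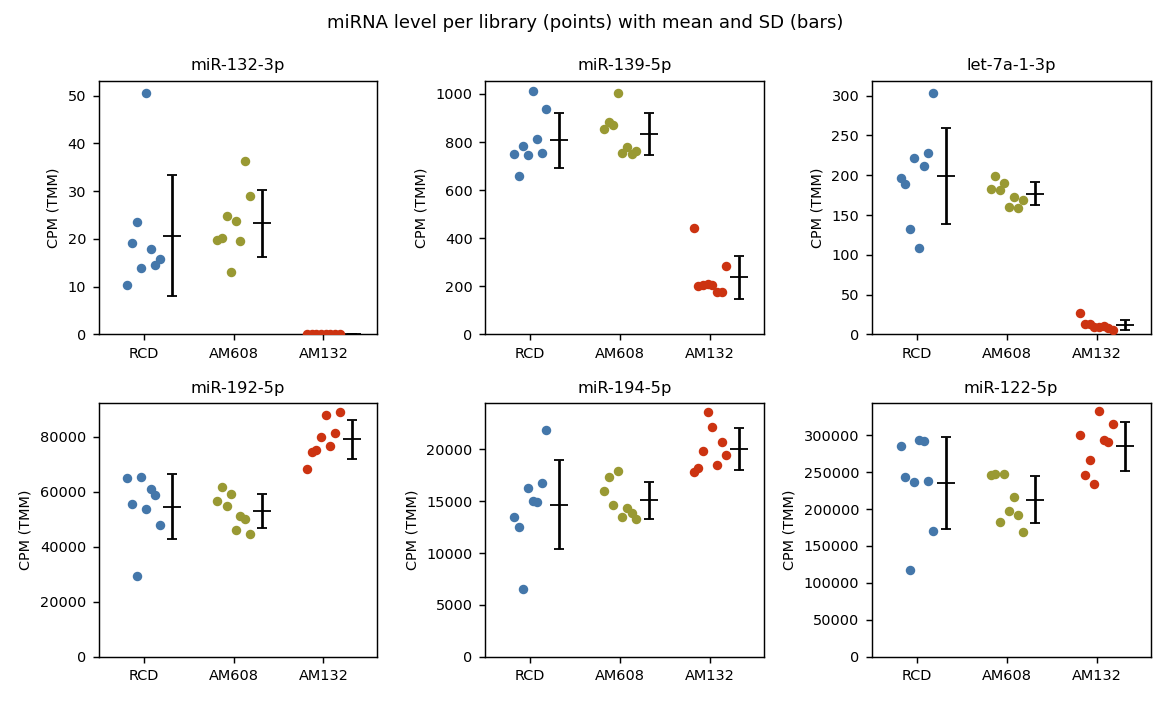
Levels of 6 miRNAs in each library, in CPM on linear axes from 0, by group, with points for libraries and the mean ± SD (n = 8 each). miR-132-3p is at 0 in all 8 AM132 libraries, and let-7a-1-3p falls from a mean of 176.8 CPM in AM608 to 11.96 CPM in AM132.

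Of the 18 miRNA lists tested, the cluster of miR-132 and miR-212 was the only one called in AM132 against AM608. Of its 4 members, 2 were lower over all miRNAs and 3 when adjusted over the list alone (camera adjusted p = 3.39e-03, and adjusted p = 0.602 with an estimated correlation). The list holds miR-132-3p, the target of the oligonucleotide, and its mean log2 fold change of −3.19 lies far below its median of −1.04. The list was not tested without that member, so the call does not speak for the cluster as a whole. Hepatocyte-abundant miRNAs had 1 of 12 members higher (miR-192-5p) and 1 lower (miR-455-3p, −2.56), with 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.11). The clusters of miR-192, miR-194 and miR-215 had 2 of 5 members higher, and 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.11). Both lists reached camera adjusted p = 0.0395 without RCD library 3, at the preset correlation. With all libraries and an estimated correlation the camera adjusted p was 0.854 for both. miRNAs reported higher in fatty liver had 3 of 19 members lower, among them miR-34a-5p (−0.75, edgeR adjusted p = 9.15e-04) and miR-205-5p (−1.55, 9.75e-03), and the list was not called (camera adjusted p = 0.32). Lipid and sterol miRNAs had 1 of 20 higher (miR-185-5p) and 1 lower (miR-34a-5p), with a camera adjusted p of 0.41. The mesenchymal marker list had 2 of 9 lower, miR-199a-3p at −0.74 (edgeR adjusted p = 4.5e-03) and the closely related miR-199b-3p, with a camera adjusted p of 0.233. These 2 are not independent members. The leukocyte, erythroid, muscle, miR-29 and miR-183 cluster lists were not called (camera adjusted p = 0.872, 0.828, 0.967, 0.415 and 0.828), nor was the Dlk1-Dio3 list (0.335).

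In obese AM608 against lean RCD liver, miRNAs of the imprinted Dlk1-Dio3 cluster were lower, and a group that includes miR-149-5p, miR-205-5p, miR-582-3p and both arms of miR-802 was higher. All 23 tested members of the Dlk1-Dio3 cluster fell, with miR-299a-3p (outside the list, same region) at −2.82, miR-411-5p at −2.67 and miR-376b-3p at −3.30 on the log2 scale. miR-149-5p rose from 57.8 to 272.8 CPM, a log2 fold change of 2.24 (SE 0.149, edgeR adjusted p = 4.63e-11). miR-802-5p, reported to be raised in obese liver, rose by 1.93 and miR-802-3p by 2.24 (edgeR adjusted p = 5.34e-05 and 3.23e-08). miR-21a-5p, the third most abundant miRNA, fell from 106100 ± 18050 to 66200 ± 8142 CPM (−0.68, edgeR adjusted p = 3.18e-05, n = 8 each).

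The edgeR test called 121 of 421 miRNAs, 57 higher and 64 lower in AM608 than in RCD, with 10 higher and 42 lower by a log2 fold change above 1 in size. miR-205-5p was 1.95 CPM in RCD and 55.9 CPM in AM608 (4.83, SE 0.481, edgeR adjusted p = 3.23e-08), and miR-582-3p rose by 4.52 (2.85e-09) with miR-582-5p by 3.69 (5.74e-08). Further higher miRNAs were miR-676-3p (1.40), miR-676-5p (1.19), miR-744-5p (0.64), miR-152-3p (0.60) and miR-107-3p (0.81), all with edgeR adjusted p of 6.46e-06 or less. miR-185-5p (−0.96) and miR-674-3p (−0.99) were lower, as were the cluster members miR-379-5p (−2.53), miR-411-3p (−2.96), miR-379-3p (−2.64), miR-134-5p (−2.74) and miR-541-5p (−2.66), with edgeR adjusted p of 7.67e-06 or less. Mir379 (GRCm38 chromosome 12, 109709060 to 109709125) and Mir411 (109710175 to 109710256) are intergenic, and Mir541 (109742409 to 109742498) lies in the non-coding gene Mirg. Mir149 lies in Gpc1 (chromosome 1, 92850378 to 92850443). Without RCD library 3 and AM132 library 8, left out together after the data had been seen, 140 miRNAs were called and 113 were shared with the 121.

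The Dlk1-Dio3 list was called as lower in AM608 than in RCD with a median log2 fold change of −2.91 (camera adjusted p = 2.77e-17, and adjusted p = 0.602 with an estimated correlation), with 23 members also lower when adjusted over the list alone. RCD library 3 had the highest score of that list (3.67, other RCD libraries up to 1.72). It also had the highest neuronal marker score, 4.17 against a median of 0.59 over the RCD libraries (lowest −0.64), −0.37 in AM608 and −0.49 in AM132, and the lowest hepatocyte-abundant score, −0.96 against a median of 0.01. RCD library 4 came next in both the Dlk1-Dio3 and the neuronal score, at 1.72 and 1.68. The preset-correlation call held when each single library was left out, but without RCD library 3, left out after the data had been seen, the median was −2.16 (23 of 23 lower). That fit keeps RCD library 4, so it does not test for RNA of other cells in the remaining RCD libraries. miRNAs reported higher in fatty liver had 8 of 19 higher and 1 lower (median 0.42, camera adjusted p = 0.048, and adjusted p = 0.854 with an estimated correlation), with miR-205-5p, miR-107-3p, miR-103-3p (0.38) and miR-802-5p higher and miR-21a-5p lower. That call was lost when most single libraries were left out (for RCD 3, camera adjusted p = 0.0915). The insulin and glucose list had 6 of 14 higher and 2 lower, and 8 and 3 when adjusted over the list alone (camera adjusted p = 0.105), with let-7d-5p up by 0.56 and miR-107-3p by 0.81. The let-7 family had 4 of 9 higher and 1 lower (camera adjusted p = 0.11), with let-7f-5p up by 0.28 (edgeR adjusted p = 5.8e-03). Hepatocyte-abundant (2 higher and 1 lower of 12), lipid and sterol (4 and 2 of 20) and fibrosis-related (3 and 2 of 12) lists were not called (camera adjusted p = 0.828, 0.686 and 0.828). The miR-30 family had 2 of 5 lower (camera adjusted p = 0.464), and the miR-17/92, leukocyte, erythroid, mesenchymal and biliary lists were not called (0.553, 0.872, 0.41, 0.828 and 0.41).

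**Figure D2:**
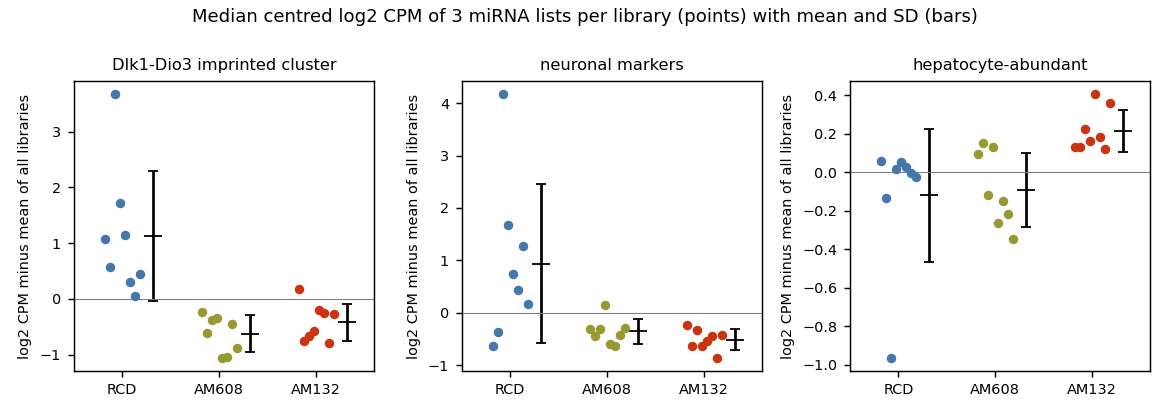
Scores of 3 miRNA lists in each library, as the median over members of log2 CPM centred on each miRNA's mean, by group, with points for libraries and the mean ± SD (n = 8 each). The Dlk1-Dio3 score had a median of 0.83 in RCD, −0.53 in AM608 and −0.43 in AM132.

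In AM132 against lean RCD liver, the Dlk1-Dio3 cluster was again lower and miR-149-5p and miR-802 again higher, while 7 of the 9 tested passenger strands of let-7 were lower. The 7 count let-7a-1-3p and let-7c-2-3p apart, whose values may come from the same reads. miR-149-5p was higher than in RCD at 249.5 CPM (2.11, edgeR adjusted p = 5.08e-11), miR-802-3p by 2.28 (2.14e-08) and miR-582-3p by 2.84 (1.15e-06). miR-582-5p, which was 13.2 CPM in AM608, was 1.09 CPM in AM132 and 1.01 CPM in RCD (0.09, edgeR adjusted p = 0.878). let-7a-1-3p fell by 4.06 on the log2 scale and miR-139-5p had a log2 fold change of −1.76 (edgeR adjusted p = 3.83e-12 and 2.14e-09).

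The edgeR test called 144 of 421 miRNAs, 65 higher and 79 lower in AM132 than in RCD. With library totals in place of TMM factors the split was 27 higher and 105 lower, with a shift of −0.19 in the median of all tested miRNAs. miR-205-5p rose by 3.27, miR-107-3p by 0.98, miR-744-5p by 0.56, miR-676-3p by 0.86, miR-152-3p by 0.56 and miR-1981-3p by 0.75 (edgeR adjusted p of 3.38e-05 or less). Lower miRNAs with the smallest p included let-7b-3p (−1.98), let-7f-1-3p (−2.48), miR-30e-3p (−0.83), miR-25-3p (−0.67), miR-299a-3p (−2.41) and miR-455-3p, which fell from 712 ± 210 CPM in RCD to 83.8 ± 96.9 in AM132 (−3.09, edgeR adjusted p = 3.64e-06, n = 8 each). All 23 Dlk1-Dio3 members were lower (median −2.61, camera adjusted p = 1.57e-11, and adjusted p = 0.795 with an estimated correlation). Without RCD library 3, which had the highest Dlk1-Dio3 (3.67) and neuronal marker (4.17) scores, the median was −1.86 and 20 of 23 were lower. RCD library 4, next in both scores at 1.72 and 1.68, was kept in that fit. The insulin and glucose list had 8 of 14 higher and 1 lower (median 0.28, camera adjusted p = 0.048, and adjusted p = 0.854 with an estimated correlation). That call was lost when most single libraries were left out (for RCD 3, camera adjusted p = 0.0915) and with RLE factors (0.0564). The list included let-7d-5p (0.57), miR-107-3p, miR-103-3p (0.33) and miR-802-5p (1.95). Hepatocyte-abundant miRNAs had 4 of 12 higher and 1 lower (camera adjusted p = 0.105). Mesenchymal markers had 4 of 9 lower, including miR-145a-5p at −0.61, miR-199a-3p at −0.56 and the closely related miR-199b-3p (camera adjusted p = 0.233).

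A set of miRNAs that differed between AM608 and RCD differed in the opposite direction between AM132 and AM608. Both comparisons use the AM608 libraries, which gives a negative relation by chance. The correlation across the 421 miRNAs, which are not independent replicates, was r = −0.261, against a median of −0.488 in 50 simulations of unchanged groups. The covariance was −0.216 against a simulated −0.0403, a difference of −0.176, and the correlation with the AM608 libraries split into sets of 4 was −0.241 (70 splits, range −0.374 to −0.116). miRNAs called in both comparisons numbered 19, all in opposite directions, where 7.32 opposite and 7.62 same-direction calls are given by independent lists. The shared AM608 libraries push joint calls towards opposite directions, so independent lists give no reference for the direction. Simulations of unchanged groups give none either, since with almost nothing called they held 0 joint opposite calls. Among them miR-582-5p, miR-676-5p, miR-34a-5p and miR-205-5p were higher in AM608 than in RCD and lower in AM132 than in AM608. miR-185-5p, miR-674-3p, miR-200b-5p and miR-148a-5p went the other way. For tRFs r was −0.253 (simulated −0.491), and the split value of −0.133 ranged from −0.337 to 0.0692.

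In tRFs, single short 5′ fragments of tRNA-LysTTT and tRNA-Ala were higher in AM132 than in AM608, and a fragment of tRNA-Ser was lower. As lists, LysTTT tRFs (2 of 15 higher) and Ala tRFs (5 higher and 2 lower of 19) were not called (camera adjusted p = 0.524 and 0.239). tRF-21-PS5P4PW3B (GCCCGGATAGCTCAGTCGGTA, the 5′ end of tRNA-LysTTT) was 2873 ± 1720 CPM in AM132, 925.7 ± 228 in AM608 and 2448 ± 1090 in RCD (n = 8 each). tRF-18-PS5P4P0K, a shorter fragment from the same end, averaged 4890 ± 6820 CPM in AM132 and 939.5 in AM608. Library 8 of AM132, at 21480 CPM, carried much of that mean, which was 2519 ± 1346 CPM without it (n = 7, left out after the data had been seen). Only 48.4% of that library's tRF counts were in tested tRFs, against 87.0% or more elsewhere, and scaled to all tRF counts its level was 10850 CPM. tRF-16-S3M830E, from the 5′ end shared by tRNA-SerAGA and tRNA-SerTGA, fell from 6271 ± 1375 to 1630 ± 502 CPM. The nuclear LysTTT genes n-TKttt22 and n-TKttt23 lie on chromosome 13 (GRCm38, 21971788 to 21971860 and 21907940 to 21908012), and fragments cannot be assigned to 1 gene copy.

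The edgeR test called 15 of 295 tRFs, 12 higher and 3 lower (19 and 1 with the library sizes of the miRNA table, a shift of 0.26 in the median of all tested tRFs). The log2 fold changes were 1.63 for tRF-21-PS5P4PW3B (SE 0.293, edgeR adjusted p = 1.01e-03), 2.38 for tRF-18-PS5P4P0K (4.2e-03), 2.24 for the Ala 5′ fragment tRF-20-R29P4P9L (0.0103) and 1.31 for the His internal fragment tRF-30-34HWH3RXSINH (0.0183). tRF-16-S3M830E had −1.95 (SE 0.219, edgeR adjusted p = 5.31e-07), the Ala 5′ fragment tRF-24-R29P4P9LH9 −0.68 (0.0229) and the Ala 3′ fragment tRF-22-WEKSP1852 −1.05 (0.0335). The most abundant LysTTT tRFs, tRF-16-JMRPFQD, tRF-19-PS5P4PJ4 and tRF-18-1SS2PMX, did not pass (−0.09, 0.61 and −0.03, edgeR adjusted p = 0.806, 0.253 and 0.928). Library 8 of AM132 held the highest AM132 values of tRF-21-PS5P4PW3B, tRF-18-PS5P4P0K and tRF-20-R29P4P9L, and without it 6 tRFs were called. The AM132 means without it were 2297 ± 592 CPM for tRF-21-PS5P4PW3B and 1031 ± 221 CPM for tRF-20-R29P4P9L (n = 7). Library 8 held 12360 CPM of tRF-20-R29P4P9L, whose log2 fold change ran from 0.9365 to 2.475 with each library left out in turn. Leaving out AM608 3 or 6 gave 6 called tRFs, AM608 7 or 8 gave 4, AM608 1 gave 8, and AM608 2, 4 or 5 gave 9. GluTTC fragments lay lower as a set (27 tested, median −0.42, camera adjusted p = 2.96e-04, and adjusted p = 0.496 with an estimated correlation), though no single one was called. The 5′ fragments had 8 higher and 2 lower of 55, a median of −0.13 and a mean of 0.17 that differ in sign (camera adjusted p = 0.264). The calls of tRF-22-WEKSP1852 and tRF-24-R29P4P9LH9 were each lost without several single libraries: for the former AM132 4, 7 or 8 or AM608 4 to 8 (edgeR adjusted p up to 0.0731), for the latter AM132 1 or AM608 1, 3, 7 or 8. The call of tRF-30-34HWH3RXSINH was lost without AM608 7 or 8 (edgeR adjusted p = 0.0559 and 0.053).

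**Figure D3:**
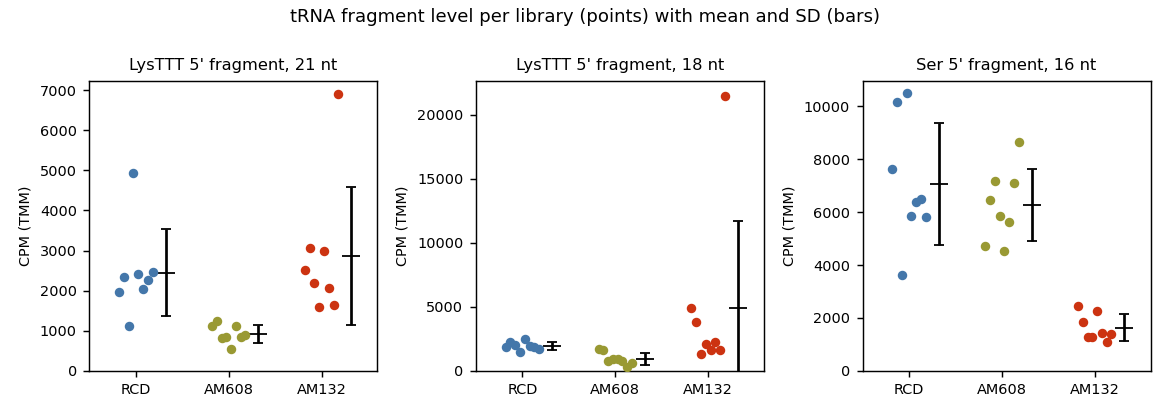
Levels of 3 tRFs in each library, in CPM on linear axes from 0, by group, with points for libraries and the mean ± SD (n = 8 each). Where the mean less the SD lies below 0, as for tRF-18-PS5P4P0K in AM132 with a mean of 4890 CPM, the lower bar is cut off at 0.

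In AM608 against RCD, 5′ fragments were lower and His fragments higher. tRF-21-PS5P4PW3B fell by 1.40 on the log2 scale (edgeR adjusted p = 8.81e-03) and tRF-20-R29P4P9L by a log2 fold change of −1.86 (0.0298), both opposite to their change in AM132 against AM608, as was tRF-16-R29P4PE (−1.23 and 1.37), singled out after its values were seen. The His internal fragment tRF-21-V47PU9XWE rose by 1.00 (edgeR adjusted p = 8.81e-03), the LysCTT internal fragment tRF-18-S8V0J8DR by 0.94 (0.0146), tRF-18-HRH7MSD2 of tRNA-SerGCT by 1.26 (0.0166) and tRF-18-HSQSD2D2 by 0.59 (0.0166). tRF-16-PJ5830E (−1.24, edgeR adjusted p = 0.0146) and tRF-16-R9JP9PD (−1.54, 0.0191), which matched no parent, and the Leu 5′ fragment tRF-20-RPM830MM (−1.28, 0.0253) were lower. The edgeR test called 13 of 295 tRFs, 5 higher and 8 lower (12 and 7 with library totals, 43 and 2 with the library sizes of the miRNA table, a shift of 0.34), and 5′ fragments as a set had 5 of 55 lower and 11 lower when adjusted over the list alone (median −0.57, camera adjusted p = 4.08e-09, and adjusted p = 0.0456 with an estimated correlation). GluTTC fragments had 1 of 27 lower (median −0.39, camera adjusted p = 0.0162, and adjusted p = 0.659 with an estimated correlation). The 11 tested His fragments had 1 higher and 4 higher when adjusted over the list alone (camera adjusted p = 2.92e-04, and adjusted p = 0.0456 with an estimated correlation). Internal fragments had 2 of 124 higher (camera adjusted p = 3.99e-04, and adjusted p = 0.081 with an estimated correlation). The count was 31 without AM132 8, 24 without RCD 3, 21 without AM608 1, and 44 without RCD 3 and AM132 8 together, 13 of them shared with the first 13. The call of tRF-20-RPM830MM was lost without AM608 2, 4, 5, 6 or 8 or RCD 4 (edgeR adjusted p up to 0.0828) and that of tRF-16-R9JP9PD without AM608 4, 5 or 6 or RCD 4 or 8. Without a filter on low counts tRF-21-PS5P4PW3B (edgeR adjusted p = 0.12), tRF-21-V47PU9XWE (0.0749) and tRF-18-S8V0J8DR (0.12) also lost their calls. The number of calls was 6 without AM608 5 or 6, 7 without RCD 4, and 8 without AM608 8, RCD 2 or RCD 8.

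AM132 livers held less of the GluTTC 5′ fragment tRF-26-86J8WPMN1EE, and more His fragments, than lean livers. GluTTC fragments as a list were also lower, a call lost with an estimated correlation (camera adjusted p = 0.283). The share of tRF counts from tRNA-Glu was 22.9 ± 2.79% in AM132, 27.8 ± 4.92% in AM608 and 29.4 ± 7.66% in RCD (range 13.9 to 38.7%, which covers the AM132 range of 19.4 to 27.4%), and that from tRNA-His 2.51 ± 1.14%, 1.77 ± 0.331% and 1.21 ± 0.206% (n = 8 each). tRF-26-86J8WPMN1EE was lower in AM132 than in RCD (102900 ± 33680 CPM, −0.85, edgeR adjusted p = 0.0172). The edgeR test called 45 of 295 tRFs, 18 higher and 27 lower (42 and 22 with library totals, a shift of 0.19 in the median of all tested tRFs, and 142 and 12 with the library sizes of the miRNA table, a shift of 0.62). GluTTC fragments had 11 of 27 lower (median −0.85, camera adjusted p = 8.97e-08, and adjusted p = 0.283 with an estimated correlation), with 1 higher and 15 lower when adjusted over the list alone. GluCTC fragments had none of 33 called (median 0.07, camera adjusted p = 0.524), and all Glu fragments together had 11 of 60 lower (median −0.26, camera adjusted p = 0.0138, and adjusted p = 0.496 with an estimated correlation), a median that turned to 0.41 with the library sizes of the miRNA table. His fragments had 6 of 11 higher (camera adjusted p = 1.78e-04, and adjusted p = 0.0456 with an estimated correlation), with tRF-30-34HWH3RXSINH at 1.36, tRF-21-V47PU9XWE at 1.00 and tRF-19-V47PU9J8 at 0.81. 5′ fragments had 2 higher and 19 lower of 55 (12 and 9 with the library sizes of the miRNA table), and 4 and 25 when adjusted over the list alone (camera adjusted p = 6.15e-10, and adjusted p = 0.0456 with an estimated correlation). tRF-16-S3M830E fell by 2.12 (edgeR adjusted p = 1.09e-07), tRF-20-RPM830MM by a log2 fold change of −2.06, tRF-16-R9JP9PD by −2.38 and tRF-16-PJ5830E by −1.66, while tRF-16-MNH5SYD rose by 1.59 (6.64e-04) and tRF-18-HRH7MSD2 by 1.08 (0.0157).

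Fragments of tRNA-LysTTT, summed per library, were lower in AM608 than in RCD by the exact permutation test, a call that was lost with total tRF or miRNA counts as the library size and with edgeR. The mean log2 CPM was 15.3 ± 0.131 in AM608 against 15.53 ± 0.0639 in RCD, a difference of −0.23 (two-sided exact permutation test, p = 0.00186, Benjamini-Hochberg adjusted over 3 comparisons 0.00559), and 1 of 8 AM608 libraries lay above the RCD mean. AM132, at 15.6 ± 0.417, was above AM608 by 0.29 (exact permutation p = 0.0382, adjusted 0.0573), which failed the correction, with 7 of 8 libraries above the AM608 mean. AM132 and RCD differed by 0.07 (exact permutation p = 0.796). The LysTTT tRF sum AM608 vs RCD was −0.12 with total tRF counts (exact permutation p = 0.0729) and turned to 0.18 with total miRNA counts as the library size (exact permutation p = 0.19), and edgeR did not call the sum (−0.23, adjusted p = 0.096). Without AM132 library 8 the LysTTT tRF sum AM132 vs AM608 was 0.16 (exact permutation p = 0.071) and the LysTTT tRF sum AM132 vs RCD turned to −0.07. That library was highest in the group at 16.52, scaled on the 48.4% of its tRF counts in tested tRFs, and at 15.54 per all tRF counts lay below the highest of the others (15.73). With total tRF counts the LysTTT tRF sum AM132 vs AM608 was 0.25 (exact permutation p = 0.0014, unadjusted). As a list, LysTTT tRFs had 2 of 15 higher in AM132 than in AM608, a median of −0.03 and a mean of 0.34 that differ in sign (camera adjusted p = 0.524), and LysCTT tRFs were not called (24 tested, camera adjusted p = 0.549).

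The total of tRF counts relative to miRNA counts passed the correction over 3 comparisons in none of them. The log2 ratio averaged −7.61 ± 0.557 in AM132, −7.65 ± 0.177 in AM608 and −7.95 ± 0.288 in RCD, and the exact permutation p was 0.0284 for AM608 against RCD (0.30, adjusted 0.0853, 8 of 8 libraries above the RCD mean). Without AM132 library 8 the tRF to miRNA ratio AM132 vs AM608 turned from 0.04 to −0.14. From the medians of tested features in place of totals, the tRF to miRNA ratio AM132 vs AM608 was 0.44 (exact permutation p = 0.00233, unadjusted) and the tRF to miRNA ratio AM132 vs RCD 0.80 (exact permutation p = 3.11e-04, unadjusted). No correlation of miR-194-5p with summed LysTTT tRFs passed the test at 8 libraries per group, within AM132 (r = −0.33, exact permutation p = 0.442, and rho = −0.52, p = 0.197), AM608 (r = 0.59, p = 0.115, and rho = 0.62, p = 0.115) or RCD (r = 0.06, p = 0.869, and rho = 0.21, p = 0.619). Without the 2 libraries farthest from the median of miR-194-5p, r was −0.14, 0.66 and 0.57. The 3 correlations had adjusted p of 0.663, 0.345 and 0.869, and with library totals the AM608 value turned to −0.60.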

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

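The tests of RCD library 3 and of sequence matches and normalization in this part, and their decision rules, were set after the results had been seen, whereas the splits of the libraries were chosen before. A sample is listed here when it lay further from its group than Dixon's test allows; chance gives this in about 1 in 20 groups, 14.85 of the 297 tested, and 32 were found, 12 of them in RCD library 3 and 10 in AM132 library 8.

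RCD library 3 stood apart from the other RCD libraries. It was the lowest in log2 CPM of let-7f-5p (14.87), miR-192-5p (14.84), miR-194-2-3p (6.10), miR-194-5p (12.68) and tRF-26-86J8WPMN1EE (16.02), and the highest in miR-132-5p (5.14) and miR-582-3p (2.69). Its scores were −0.96 for hepatocyte-abundant miRNAs, −1.05 for the clusters of miR-192, miR-194 and miR-215, −0.51 for the miR-30 family, 1.74 for the p53-responsive list and 3.67 for the Dlk1-Dio3 cluster. miR-7b-5p reached 1414 CPM there (12.02 at most in the other RCD libraries), miR-218-5p 1389 (17.1), miR-10b-5p 4292 (391) and miR-615-3p 179 (3.58), all 4 chosen after their values were seen. Against the median of the other 7 libraries, lists of other cell types moved apart: neuronal 4.06, erythroid 1.45, pancreatic 1.07, leukocyte 1.02, muscle 0.42, mesenchymal 0.10, endothelial −0.33 and biliary −1.62. A lower share of hepatocytes alone would raise the others alike, and the biliary and endothelial lists did not rise. The biliary list holds 5 miRNAs, and its score ran from −1.22 to 1.23 within the AM608 libraries. Its −1.62 in a single library therefore does not decide the question. The ratio of miR-124-3p to miR-9-5p was 0.016 (8.47 against 530 CPM), where brain neurons would carry more miR-124-3p. No brain library was analysed here to set beside this ratio, so it does not decide on brain neurons as the source. miR-138-5p reached 34.3 CPM in RCD library 3 (0.785 at most in the other RCD libraries) and miR-129-5p 258 CPM (19.8), both given after their values were seen. RNA from another tissue stays open: the hepatocyte-abundant miRNAs lay lower by −0.96, but that score is among the values by which the library stands apart, so it is no test. The design names no biological explanation for a single library, so none was tested beyond these sources of RNA.

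AM132 library 8 held 80578 tRF counts (next in the group 41236), 4099 tRFs with a count (1967), 12.4 tRF counts per 1000 miRNA counts (5.35), and 2.84% in its most abundant tRF (10.1% in the next lowest). Only 48.4% of its tRF counts were in tested tRFs, on which CPM is scaled (87.0 to 90.4% in the other libraries), so about 1 log2 unit of its tRF levels comes from that scaling. Its log2 CPM was the highest of the group for the LysTTT sum (16.52, next 15.86, but 15.54 per all tRF counts against 15.73 at most in the others), miR-148a-5p (8.37), tRF-18-PS5P4P0K (14.40), tRF-20-R29P4P9L (13.60) and tRF-21-PS5P4PW3B (12.77), and the lowest for tRF-26-86J8WPMN1EE (14.96). Single values apart from their group were miR-132-5p in AM132 5 (4.04), miR-212-3p in AM132 4 (−1.85), tRF-21-V47PU9XWE in AM132 6 (9.75), miR-379-3p in AM608 5 (−0.77), tRF-18-1SS2PMX and tRF-20-R29P4P9L in AM608 3 (11.78 and 8.28), miR-187-3p in RCD 8 (2.97) and tRF-18-HRH7MSD2 in RCD 1 (11.71). The muscle score of AM608 1 was −0.11 and the neuronal score of AM608 4 was 0.15.

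The 22 miRNAs lower in AM132 than in both other groups included miR-132-3p, miR-212-3p, miR-139-5p, miR-455-3p, miR-25-3p, miR-30e-3p, miR-199a-3p and 7 let-7 passenger strands. Normalization is argued against as the whole cause, since a library scaling moves all miRNAs alike. Such a set was chosen in 4 random libraries of each group and measured in the other 4, to keep the choice of low values out. Over 20 such draws, of 8 to 19 miRNAs each, its median log2 fold change against AM608 was compared with that of the other tested miRNAs. The gap had a median of −1.52 (−2.22 to −0.67, SD of the others 0.45). These sets are smaller than the 22. For the 20 of the 22 outside the miR-132 and miR-212 arms the gap was −0.875 with library totals (SD of the others 0.39), in the same libraries that chose them. The arms of miR-132 and miR-212 and let-7c-2-3p, which shares its reads with let-7a-1-3p, were left out of the sequence match. For the other 19 of the 22, the best ungapped match of the arm's side of the hairpin (the whole hairpin where the name gives no arm) with miR-132-3p scored 6.53 ± 1.31 (n = 19) against 5.01 ± 1.04 (n = 383) for other tested miRNAs (permutation p = 1e-05, the smallest that 100000 resamples can give). Outside the let-7 family it was 6.46 ± 1.20 (n = 13) against 5.02 ± 1.03 (n = 373, permutation p = 2e-05). A match with miR-608 was not higher (permutation p = 0.95 for the 19, and 0.63 for the 13 outside the let-7 family), which argues against a resemblance that extends to that target. No shuffled sequence and no sequence of like base composition was scored, so the match tests do not speak for other targets or for base composition. With arms only and scores adjusted for length, the permutation p was 1e-05 and 2e-05 for miR-132-3p, and 0.89 and 0.37 for miR-608. Members were permuted as if independent, though the 19 hold several let-7 passenger strands and the related pairs miR-199a-3p with miR-199b-3p and miR-23a-3p with miR-23b-3p. Related hairpins can score alike, so the low permutation p-values are likely too small. Binding of the anti-miR-132 oligonucleotide to partly matching miRNAs is a candidate explanation, and loss in the liver and masking during library preparation cannot be separated here.

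For the 8 miRNAs lower in AM608 than in both other groups (miR-148a-5p, miR-185-5p, miR-194-2-3p, miR-200b-5p, miR-26a-5p, miR-30e-5p, miR-455-5p and miR-674-3p, the set chosen after its values were seen), the match with miR-608 scored 5.75 ± 1.28 against 5.38 ± 1.17 (permutation p = 0.22). For the 3 tRFs lower in AM608 (tRF-21-PS5P4PW3B, tRF-20-R29P4P9L and tRF-16-R29P4PE) it scored 6.67 against 4.96 (permutation p = 0.0087), but these come from only 2 parent groups. Whether the control oligonucleotide lowered any of these through its sequence therefore cannot be told apart from other causes, since the miRNA p missed the threshold and the tRFs are too few. The place of miR-194-2-3p among the 8 miRNAs is fragile. Its log2 fold change in AM608 against RCD was −0.38, a call lost when any of 14 single libraries was left out. In all, 7 match tests and 4 adjusted for length were run, on 402 of the 407 tested miRNAs with a hairpin (386 without let-7, 375 and 359 for arms only) or on 295 tRFs.

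The libraries of each comparison were split into 8 and 8 in 100 ways, the real one included. In each of the 6 tests only the real split gave as many calls. A random split is thus an unlikely source of these counts, though 1 in 100 is the smallest share this test can give. It says nothing on causes that run with the groups, which also follow the order of the libraries in the column names. The real and highest other counts were 52 and 1, 121 and 36, and 144 and 54 for miRNAs (AM132 against AM608, AM608 against RCD, AM132 against RCD) and 15 and 6, 13 and 4, and 45 and 23 for tRFs.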

How the results depend on the processing

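The fits without RCD library 3 and AM132 library 8 together, the lists with each library left out, the list medians under other scalings, the Dlk1-Dio3 median without RCD 3, the isoacceptor sums without AM132 8 and the parent tRNAs were chosen after the data had been seen, and the other alternatives before; all of those were run. Of the values that answer a comparison under an alternative, 451 kept their direction and side of the threshold (counts within 1.5 times), 29 lost and 12 gained the call, 56 moved and 4 reversed. For single named features the numbers were 3388 the same, 77 lost, 22 gained and 62 reversed, the reversals being of values that had not passed the test. Unless a cause is given, the cause was not tested. Depth limits the tRFs, whose libraries held 20580 to 80578 counts, more than the miRNAs.

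With limma voom, 101 miRNAs were called in AM132 against AM608 and 38 tRFs in AM608 against RCD, and miR-212-5p passed in AM132 against AM608 (−0.46, limma adjusted p = 0.0436). The miR-194-5p AM132 vs AM608 comparison passed as well (0.45, limma adjusted p = 1.66e-04). tRF-18-1SS2PMX was 0.021 there. With DESeq2 51 miRNAs were higher and 103 lower in AM132 against RCD, and miR-212-3p was −0.022 in AM608 against RCD, and with RLE factors −0.030, with tRF-18-1SS2PMX at 0.016 in AM132 against AM608. With library totals, 91 miRNAs were called in AM132 against AM608, miR-212-5p passed (−0.73, edgeR adjusted p = 0.0301), and miR-192-5p was 0.037 in AM608 against RCD. miR-132-5p and miR-212-5p were −0.069 and −0.046 in AM132 against RCD, and tRF-18-1SS2PMX was 0.047, 0.069 and 0.12 in the 3 comparisons (AM132 against AM608, AM608 against RCD, AM132 against RCD).

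Without a filter, miR-212-3p lost its call in AM132 against AM608 (−1.61, edgeR adjusted p = 0.0734), and 208, 5 and 191 tRFs were called in the 3 comparisons. In AM608 against RCD tRF-16-JMRPFQD was 0.12, tRF-19-PS5P4PJ4 0.16 and tRF-18-1SS2PMX 0.27, the last 0.094 in AM132 against RCD. With a mean CPM of at least 10, which for tRFs is looser and tests 2251 of them, 5, 3 and 21 tRFs were called. 94 miRNAs were then called in AM132 against RCD, since fewer were tested, miR-194-5p AM132 vs AM608 passed (0.40, edgeR adjusted p = 0.0414), miR-194-5p AM608 vs RCD was −0.0028, tRF-19-PS5P4PJ4 was 0.0040 in AM608 against RCD, and tRF-18-1SS2PMX 0.11 there and 0.039 in AM132 against RCD. With only the 2 groups compared, 87 miRNAs were called in AM132 against AM608 with miR-194-5p among them (0.38, edgeR adjusted p = 8.14e-04), 31 tRFs in AM608 against RCD, and miR-212-3p was −0.036 in AM608 against RCD.

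The replicate numbers did not pair the samples. Correlations of deviations between same-numbered libraries ran from −0.421 to 0.492, with 2 to 5 of 8 above 0.1 and 1 to 3 of 8 libraries closest to their own number. With the replicate block, edgeR called 47 miRNAs in AM132 against AM608, 109 in AM608 against RCD and a count within 1.5 times of the 144 in AM132 against RCD, and 16, 19 and 33 tRFs, and tRF-18-1SS2PMX was 0.0084 in AM608 against RCD. The iMetCAT list passed in AM608 against RCD with the block (camera adjusted p = 0.034), but not without it (0.0511, and 0.496 with an estimated correlation). With the block the tRF to miRNA ratio was 0.30 in AM608 against RCD (exact sign-flip p = 0.0781) and 0.34 in AM132 against RCD (p = 0.0469), both with an adjusted p of 0.117 over 3 comparisons. The LysTTT tRF sum AM132 vs AM608 then passed (exact sign-flip p = 0.0156, adjusted over 3 comparisons 0.0234), where without the block its adjusted p of 0.0573 had not.

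Without RCD 3 and AM132 8, miR-212-3p lost its call (−1.60, edgeR adjusted p = 0.0507), miR-194-5p passed in AM132 against AM608 (0.38, 0.014) and was −0.073 in AM608 against RCD. 44 tRFs were then called in AM608 against RCD, and tRF-18-1SS2PMX was 0.097 in AM132 against AM608 and 0.012 in AM132 against RCD. With library sizes of the miRNA table, which shifted the median tRF by 0.26, 0.34 and 0.62, 45 and 154 tRFs were called in AM608 and AM132 against RCD, and the splits of higher and lower were 19 and 1, 43 and 2, and 142 and 12 in the 3 comparisons (12 and 3, 5 and 8, and 18 and 27 with TMM factors). tRF-16-JMRPFQD was 0.20, 0.14 and 0.34, tRF-18-1SS2PMX 0.20, 0.32 and 0.52 in the 3 comparisons (the last with edgeR adjusted p = 0.0262), and tRF-19-PS5P4PJ4 0.21 in AM608 against RCD. Summed per isoacceptor, 0 (6 at an unadjusted p under 0.05), 1 and 6 of 24 were called by edgeR, with fewer features tested.

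With an estimated correlation no miRNA list and 6 tRF lists were called (4 distinct, as the lists of HisGTG and of all His are the same fragments, which also makes the 13 with the preset correlation 11 distinct), and fry called 15 miRNA lists. Among features called in AM608 against RCD alone, the correlation of changes was −0.58 for miRNAs and −0.42 for tRFs; choosing features by a comparison that shares the AM608 libraries makes this more negative and no value without change was computed, so nothing is read from it. With AM608 split the correlation was −0.133 for tRFs. The LysTTT tRF sum AM132 vs AM608 was 0.29 with total miRNA counts (exact permutation p = 0.267). The LysTTT tRF sum AM608 vs RCD was 0.18 with total miRNA counts (exact permutation p = 0.19) and with total tRF counts −0.12 (exact permutation p = 0.0729). From medians the tRF to miRNA ratio AM132 vs AM608 was 0.44 (exact permutation p = 0.00233) and the tRF to miRNA ratio AM132 vs RCD 0.80 (exact permutation p = 3.11e-04), the latter being 0.48 without the most abundant features (exact permutation p = 0.0176). The correlation of miR-194-5p with LysTTT was −0.597 in AM608 with library totals.

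With each library left out, miRNA calls ran from 44 to 64, 112 to 133 and 127 to 154 in the 3 comparisons, and tRF calls from 4 to 20, 6 to 31 and 37 to 62. miR-212-3p ran from −1.80 to −1.40 in AM132 against AM608 and from −0.18 to 0.45 in AM608 against RCD, miR-212-5p from −0.58 to −0.40 (passing without AM608 4, edgeR adjusted p = 0.0443) and miR-194-5p from 0.36 to 0.43 (passing without RCD 3, edgeR adjusted p = 0.00976). In AM608 against RCD, miR-194-5p ran from −0.074 to 0.16 and miR-192-5p from −0.14 to 0.019. tRF-16-JMRPFQD ran from −0.16 to 0.011 in AM132 against AM608, and tRF-18-1SS2PMX from −0.11 to 0.030, −0.058 to 0.048 and −0.12 to 0.068. Called miRNA lists numbered 3 to 6 (3 without any 1 of AM132 1 to 7, AM608 3, 5, 6, 7 or 8, RCD 5 or 6) and tRF lists 11 to 17. The LysTTT sum ran from 0.16 to 0.34 in AM132 against AM608 (exact permutation p of 0.05 or more without AM132 1, 2 or 8 or AM608 2, 3, 5, 6, 7 or 8) and from −0.065 to 0.11 in AM132 against RCD (negative without AM132 8). The ratio ran from −0.14 to 0.12 in AM132 against AM608 (negative without AM132 8) and the tRF to miRNA ratio AM608 vs RCD from 0.24 to 0.35 (exact permutation p of 0.0575 without RCD 1, 0.0536 without RCD 4, 0.0549 without RCD 5 and 0.053 without RCD 6).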

Other observations

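The tests of parent tRNAs in this part rest on tRNA sequences added after the tables had been seen. Summed per isoacceptor, tRNA fragments of 24 isoacceptors were tested with edgeR. The sums took only fragments that matched 1 isoacceptor (65.0% of the counts), so fragments shared between isoacceptors were left out. Of such fragments, AM132 livers carried more from tRNA-HisGTG (log2 fold change 0.77, edgeR adjusted p = 0.00343), tRNA-GlyGCC (0.76, 0.0489), tRNA-ProTGG (0.77, 0.0499) and tRNA-ValCAC (1.80, 0.0469) than lean livers. They carried fewer from tRNA-GluTTC (−0.88, edgeR adjusted p = 0.0119) and tRNA-LysCTT (−0.64, edgeR adjusted p = 0.0489). All Val fragments together, shared ones included, held 3.01 ± 0.400% of tRF counts in AM132 and 2.84 ± 0.557% in RCD (n = 8 each). Without AM132 library 8, left out after the data had been seen, the calls of tRNA-HisGTG (0.57, edgeR adjusted p = 0.00213) and tRNA-GluTTC (−0.76, edgeR adjusted p = 0.0159) were the 2 left. tRNA-GlyGCC was then at 0.25, tRNA-ProTGG at 0.23, tRNA-ValCAC at 0.36 and tRNA-LysCTT at −0.52 (edgeR adjusted p = 0.261, 0.302, 0.381 and 0.0791). Fragments of tRNA-TyrGTA were higher in AM608 than in RCD (0.57, edgeR adjusted p = 0.0486), the 1 call in that comparison. Without AM132 library 8 the edgeR calls there were 5, with tRNA-AspGTC (−0.56, adjusted p = 0.024), tRNA-HisGTG (0.44, 0.0133), tRNA-PheGAA (−0.72, 0.0281), tRNA-SerGCT (0.46, 0.0444) and tRNA-TyrGTA (0.57, 0.00946). tRNA-LysTTT sums did not pass in AM132 against AM608 (0.09, edgeR adjusted p = 0.57), AM608 against RCD (−0.23, 0.096) or AM132 against RCD (−0.14, 0.266). By length, 18-nt fragments held 30.3% of tRF counts, 26-nt fragments 14.4% and 16-nt fragments 13.7%.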
